A study of Mus musculus with 6 samples.

How the data were processed

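RNA was measured in 6 libraries of bone marrow HSCs of wild-type C57BL/6 mice, 3 sorted as TMRM-high and 3 as TMRM-low. Per the labels' protocols, marrow was flushed from long bones, red cells were lysed, 1500 cells per library were sorted, RNA was purified and reverse transcribed after a full-length low-input method, cDNA was amplified by 13 cycles of PCR, and libraries made by tagmentation were sequenced as paired reads of 150 bases. Such libraries do not mark strand and carry no molecular identifiers, so reads of overlapping antisense genes cannot be told apart and PCR copies are counted as reads. Per the submitters' processing notes, Trim Galore 0.5.0, Salmon (version listed as 0.03.1) and the genome build GRCm38 were used; the annotation, settings and the step from transcripts to genes are not given in the sources used here. The deposited values are estimated counts per gene for 28786 Ensembl gene IDs, not scaled to depth, as the authors' quantification gave them, and partly not whole. They were rounded to whole numbers for the count tests. Salmon divides reads between similar transcripts, so counts of pseudogenes and close gene families can move between members.

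Gene symbols were matched for 27728 IDs, and 1058 kept their ID, which held 4.91% to 6.13% of the counts. Most of these came from a single ID, which held 4.41% to 5.40% of the counts of a library. Positions and gene types were taken from GENCODE M21 on GRCm38 for 27797 IDs. Genes were kept by edgeR's filterByExpr with the group, which left 13662. Library sizes were scaled by TMM and edgeR 4.0.16 fitted a quasi-likelihood model with the group as its only term and robust estimation (glmQLFit, glmQLFTest), in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM are computed here from the rounded counts and TMM-scaled library sizes. For a gene with no count in a group, the fold change is a lower bound against 3 counts over the group, and with 1 to 3 counts the ratio of summed CPM is given with its 95% exact binomial interval; both cover counting error only. Left-out values of these keep the library sizes of the main fit and set a group left at 0 to 3 counts.

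Gene lists for 35 pathways, cell types and states were fixed before the data were examined, as were the tests. Lists with at least 3 tested members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, which tests whether a set's genes move on balance 1 way and does not compare it with other genes. Calls held with an estimated correlation for the lists of interferon response, immediate early response, B lymphoid, G2/M, granulocyte and monocyte, mast cell, basophil and eosinophil, erythroid, HSC identity and multipotent progenitor genes. Genes named in the report follow a rule fixed before the data were examined: among called genes with a symbol that is not a predicted model, a mean of at least 5 CPM and groups that do not overlap, the 10 largest changes in each direction; in each list up to 4 called members with the smallest p, or up to 2 that did not pass; and the 4 sort markers. Not every gene the rule allows is described. Genes in the closing section that the rule does not give were chosen after their values were seen, and that section says so.

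The tests were tried on simulated counts drawn from the means, spread and library sizes of this comparison, in 5 simulations of 13662 genes with 200 changed genes each. Of unchanged genes 20 of 67160 were called. They made up 6.19% of these calls together with the calls of changed genes in the right direction, calls in the shifted list below left out. Of genes changed 1.5-fold, 8.06% were recovered, of those changed 2-fold 26.9% and of those changed 4-fold 56.4%. A gene that does not pass can therefore still differ by several-fold. A list of 30 genes shifted by 0.5 on the log2 scale was called in 5 of 5 simulations. Of 175 tests of other lists 0 were called. The simulated genes were drawn independently, so members of a list were not correlated as in real libraries. The rate of false list calls in the real comparison is therefore not measured. The libraries were drawn independently too, which takes the TMRM-high libraries as separate replicates. If they share material, the simulations do not measure the rate of false gene calls either. The biological coefficient of variation, estimated in each group alone over genes with a mean count of at least 50, was 7.24% in TMRM-high and 41.5% in TMRM-low libraries, and the model uses 1 estimate for both.

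Alternatives were RLE, upper-quartile and total-count scaling, no low-count filter and a stricter one (mean count of at least 50), DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, an adjusted p of 0.10, a minimum of 2-fold, each library left out, and removal of mitochondrially encoded, ribosomal protein and haemoglobin genes before scaling. Summing the TMRM-high libraries and summing ribosomal protein genes with their pseudogenes were chosen after seeing the data. For the latter, 361 pseudogenes were matched to 53 ribosomal protein genes by sharing at least 10% of their 31-base words. Pairs of libraries were compared by a chi-square of their counts over genes with at least 20 counts in the pair, also after thinning each library to the lowest total. The labels list the TMRM-high libraries as 3 samples and the chi-square lay above counting noise, so all 3 were kept as replicates in the main test. This does not show that they are independent, because separate amplifications of 1 RNA pool also differ by more than counting noise. All columns of the deposited table were used.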

Results

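Haematopoietic stem cells (HSCs) of wild-type C57BL/6 mice aged 6 to 8 weeks were sorted by their signal for TMRM, a dye that accumulates in mitochondria according to their membrane potential. By the labels, each library was made from 1500 bone marrow cells gated as lacking lineage markers and CD48 and carrying Sca-1, c-Kit and CD150, and 3 TMRM-high and 3 TMRM-low libraries were sequenced after a low-input protocol. The question the labels pose is how the RNA of HSCs with a high TMRM signal differs from that of HSCs with a low one. Totals of the estimated counts were 22070594, 19305225 and 14270069 in the TMRM-high libraries. They were 17779292, 15930495 and 18431567 in the TMRM-low libraries. Values per gene are in CPM, counts scaled to the size of the library, as mean ± SD over n = 3 libraries per group, and log2 fold changes are TMRM-high minus TMRM-low with their standard error (SE). Adjusted p-values for genes are from edgeR's quasi-likelihood test and those for gene lists from limma's camera, both two-sided with Benjamini-Hochberg adjustment. Nothing in the labels says that the libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which can be technical.

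The libraries labelled TMRM-high held more RNA of granulocytic, basophil, erythroid and B lineage genes and of immediate early genes, and less RNA of HSC identity genes and interferon response genes. Ribosomal protein genes ranked lower as well, but not with an estimated correlation (adjusted p = 0.37). Of 13662 genes tested, 798 were higher and 700 were lower in TMRM-high libraries, and 434 of the former and 300 of the latter differed by at least 2-fold. Of 35 gene lists fixed before the data were examined, 7 ranked higher and 6 lower than the other genes. With an estimated correlation 6 ranked higher and 3 lower. The calls of complex I (camera adjusted p = 0.37), ribosomal protein (0.37), dendritic cell (0.19) and megakaryocyte genes (0.082) were lost. The estimated correlation was 0.41 for ribosomal protein and 0.073 for complex I genes, above the preset 0.01. It was -0.074 for dendritic cell and -0.036 for megakaryocyte genes, so correlated members do not account for these 2 losses. In that setting camera also takes its degrees of freedom from the libraries rather than the genes, which lowers its power. The 3 TMRM-high libraries resembled each other far more than the 3 TMRM-low libraries did. Over genes with at least 20 counts, chi-square per degree of freedom was 3.98 to 6.74 between TMRM-high libraries and 46.0 to 51.4 between TMRM-low libraries, where counting noise alone gives about 1. With the TMRM-high libraries summed into 1, an alternative chosen after this was seen, 86 genes were higher and 42 lower. That test has 1 library in the TMRM-high group and takes its spread from the TMRM-low libraries alone, so it has less power. The named genes that lose their calls in it keep their direction, and 41 of them move by under 0.1 on the log2 scale. Summing leaves the TMRM-high level nearly unchanged by construction, so this does not show that the changes would replicate. A call lost there does not by itself show a smaller change. Without TMRM-high replicate 1, 2 or 3 the counts were 255, 269 or 250 higher and 198, 190 or 181 lower. Without TMRM-low replicate 1, 2 or 3 the counts were 1225, 1218 or 1398 higher and 985, 1063 or 1174 lower.

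**Figure D1:**
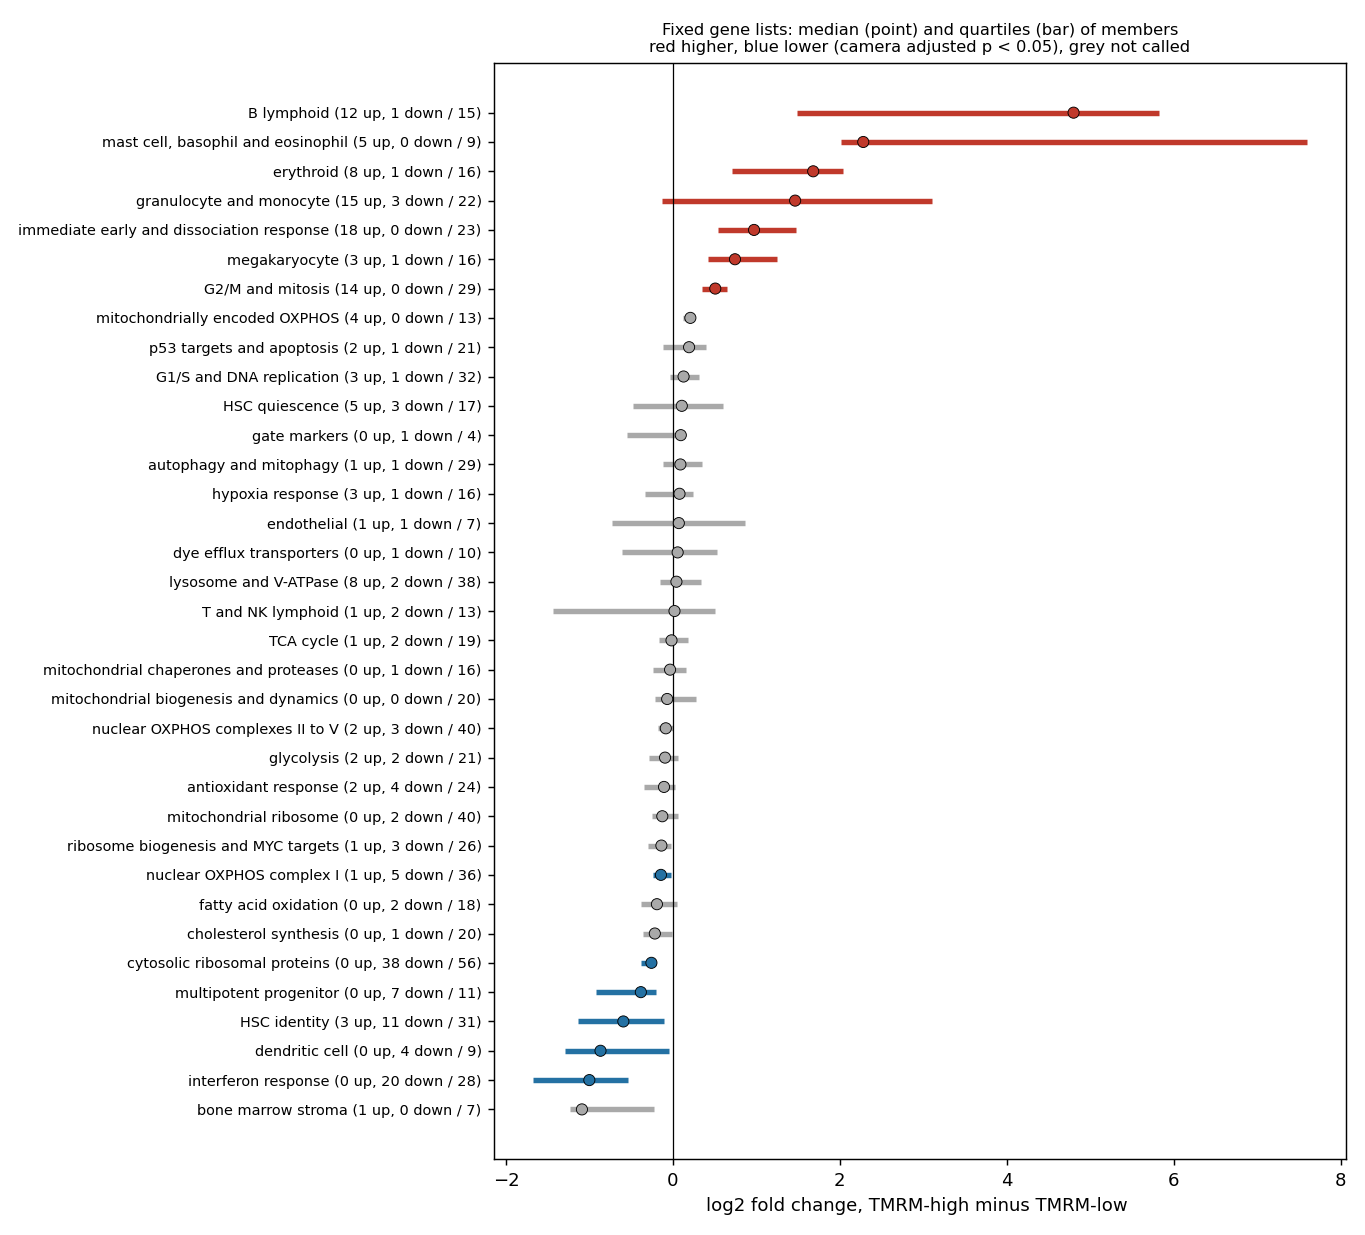
Median log2 fold change (TMRM-high minus TMRM-low, horizontal axis) of the tested members of each of 35 fixed gene lists, with bars for the quartiles over members and the number of members called up or down beside each name. The B lymphoid list has the highest median (4.80) and 5 of the 6 lists called lower have medians of -0.26 or below; the exception is complex I (-0.14).

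The largest increases included Mogat2, an acylglycerol acyltransferase (chromosome 7, 99219084 to 99238619 on GRCm38), which had 24.0 ± 2.48 CPM in TMRM-high libraries and no count in TMRM-low libraries, at least 418-fold higher against a floor of 3 counts over the group. Igkv3-10, an immunoglobulin kappa variable segment, was likewise at 0 in TMRM-low libraries and at least 331-fold higher. The iron exporter gene Slc40a1 (33.1 ± 5.72 CPM) rested on 3 counts in TMRM-low libraries, a ratio of 560 with a 95% exact counting interval of 191 to 2719. Lrg1, a granulocyte glycoprotein gene, had a ratio of 379 (129 to 1839), and the immunoglobulin constant gene Ighg3 one of 594 (164 to 4906). Tcrg-C1, a constant gene of the T cell receptor gamma locus, had a ratio of 470 (130 to 3884). The segment Ighv5-6 was at 64.6 ± 1.88 against 0.116 ± 0.200 CPM, a log2 fold change of 9.04 (SE 0.632). Among the largest decreases were Igkv4-72, with a ratio of 1210 in favour of TMRM-low libraries (217 to 47844). The natural killer (NK) cell receptor gene Klra8 had such a ratio of 319 (109 to 1548). Lower too were the NK receptor genes Klra4 (log2 fold change -6.94, SE 0.603), Klra7 (-5.00, SE 0.873) and Ncr1 (-4.21, SE 0.653). Npdc1 (-4.36, SE 0.350) and Gas6, which encodes a ligand of TAM receptor kinases (-4.31, SE 0.661), fell too. Rps16-ps2, a processed pseudogene that shares all of its 31-base words with Rps16, had no count in TMRM-high libraries and 310 ± 253 CPM in TMRM-low libraries, at least 5567-fold lower against the same floor; it did not pass without a low-count filter or with limma voom. With 1 library left out, these bounds and ratios ran from 269 to 436 for Mogat2, 213 to 345 for Igkv3-10, 361 to 1118 for Slc40a1, 244 to 756 for Lrg1 and 383 to 819 for Ighg3. They ran from 208 to 486 for Tcrg-C1, 244 to 1369 for Igkv4-72, 208 to 579 for Klra8 and 3353 to 8047 for Rps16-ps2. All of these genes passed the edgeR test with adjusted p-values between 9.4e-05 and 0.0116. The immunoglobulin segments and constant genes and the Klra genes are families of close copies, so their counts can be split between members and are uncertain. The bound for Rps16-ps2 is uncertain too, because its reads can be placed on Rps16 instead. Klra7 lost its call without TMRM-high replicate 2 and Ncr1 without TMRM-high replicate 1. Both, with Npdc1 and Gas6, lost it with the TMRM-high libraries summed.

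Among the genes of the sort markers, Ly6a, which encodes Sca-1 (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), was lower in TMRM-high libraries, at 30.3 ± 2.18 against 167 ± 7.77 CPM (log2 fold change -2.47, SE 0.103, edgeR adjusted p = 1.0e-05). Kit was at 263 ± 4.93 in TMRM-high and 248 ± 53.9 CPM in TMRM-low libraries, and Cd48 at 147 ± 2.82 and 137 ± 22.6 CPM. Slamf1, which encodes CD150, was at 5.53 ± 0.569 and 5.13 ± 3.98 CPM. None of these 3 passed the test. In all 6 libraries Cd48 had more CPM than Slamf1, which sits badly with a gate for cells without CD48 and with CD150, although RNA levels do not measure surface protein. The list of 4 sort markers was not called, with 1 lower in both countings, and its median (0.09) and its mean (-0.54) differed in sign.

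Of 31 tested HSC identity genes, 11 were lower, 3 were higher and 17 did not pass, and 13 were lower and 3 higher when adjusted over the list alone. The list ranked lower (camera adjusted p = 4.8e-06, median log2 fold change -0.59). Procr, which encodes the endothelial protein C receptor used to isolate HSCs, fell from 33.9 ± 9.84 CPM in TMRM-low to 3.57 ± 0.304 CPM in TMRM-high libraries (log2 fold change -3.25, SE 0.299). Ifitm1 was at 122 ± 1.73 against 641 ± 46.5 CPM (-2.40, SE 0.0714). The transcription factor gene Hlf was at 52.5 ± 3.79 against 152 ± 12.9 CPM (-1.53, SE 0.108). Lmo2 was at 506 ± 7.78 against 764 ± 24.5 CPM (-0.59, SE 0.0498). Of 11 multipotent progenitor genes, 7 were lower and none higher, over all genes as well as adjusted over the list alone (camera adjusted p = 0.00014). They included Emb (-0.90, SE 0.0659) and Flt3, a cytokine receptor gene of lymphoid-primed progenitors (-1.12, SE 0.108). Procr, Lmo2 and Flt3 lost their calls with the TMRM-high libraries summed.

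**Figure D2:**
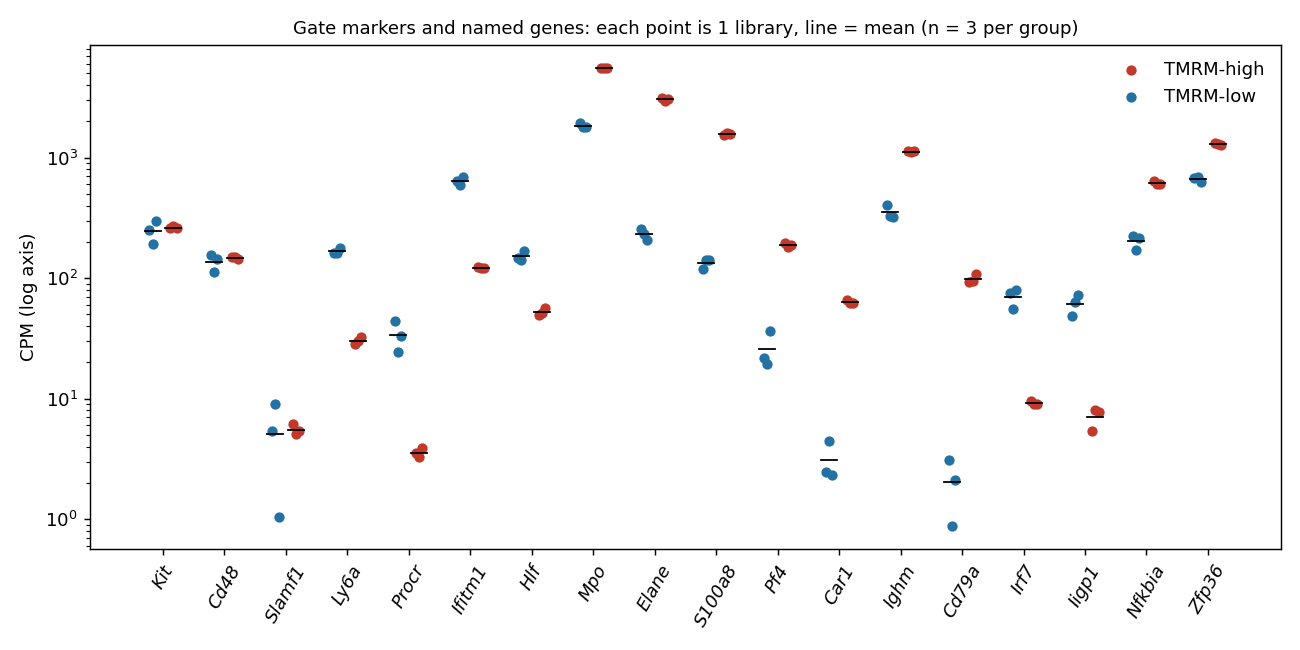
CPM on a log axis for the 4 sort markers and 14 named genes, with 1 point per library, TMRM-high in red and TMRM-low in blue, and a line at the mean of 3. Kit, Cd48 and Slamf1 overlap between the groups, while Ly6a averages 30.3 CPM in TMRM-high and 167 CPM in TMRM-low libraries.

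Granulocyte and monocyte genes ranked higher (camera adjusted p = 2.0e-07, median 1.46). Of 22 tested members 15 were higher, 3 lower and 4 not passing, and 15 were higher and 4 lower adjusted over the list alone. Elane, which encodes neutrophil elastase (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), rose from 232 ± 23.9 to 3036 ± 78.3 CPM (log2 fold change 3.71, SE 0.0820). S100a8, a subunit of calprotectin, rose from 134 ± 12.7 to 1574 ± 23.3 CPM (3.55, SE 0.0792). Mpo, which encodes myeloperoxidase, was already abundant in TMRM-low libraries at 1844 ± 66.0 CPM and reached 5534 ± 46.7 CPM in TMRM-high libraries (1.59, SE 0.0407). Ly6c2 rose by a log2 of 2.40 (SE 0.0715). Mast cell, basophil and eosinophil genes also ranked higher, with 5 of 9 members higher and none lower and 7 higher adjusted over the list alone (camera adjusted p = 4.3e-07, median 2.28). The basophil protease gene Prss34 was at 71.7 ± 2.37 against 0.192 ± 0.286 CPM (8.48, SE 0.600). The eosinophil granule gene Prg2 was at 39.4 ± 2.96 against 0.157 ± 0.176 CPM (7.92, SE 0.621). Hdc, which encodes histidine decarboxylase, was at 76.7 ± 6.03 against 12.5 ± 2.46 CPM (2.62, SE 0.193).

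Of 16 erythroid genes, 8 were higher, 1 lower and 7 not passing, and 9 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.8e-05, median 1.68). The carbonic anhydrase gene Car1 rose from 3.11 ± 1.20 to 63.5 ± 2.25 CPM (log2 fold change 4.36, SE 0.286). The globin gene Hbb-bt rose from 17.8 ± 3.71 to 49.8 ± 4.31 CPM (1.49, SE 0.205). Car2, another carbonic anhydrase gene, fell (-0.81, SE 0.0781). The megakaryocyte list ranked higher with 3 of 16 members higher and 1 lower, the same numbers as adjusted over the list alone (camera adjusted p = 0.0028, and adjusted p = 0.082 with an estimated correlation). Platelet factor 4 (Pf4) rose from 26.0 ± 9.33 to 189 ± 7.76 CPM (2.85, SE 0.234). Itga2b, which encodes CD41, rose from 59.9 ± 6.07 to 141 ± 3.63 CPM (1.23, SE 0.106). Clu fell (-1.77, SE 0.365). Clu lost its call without any 1 TMRM-high library. With the TMRM-high libraries summed, Car2, Hbb-bt, Itga2b and Clu did not pass.

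B lymphoid genes had the largest median change of the 35 lists, 4.80 as fitted and 3.97 with the 1 member that had a group at 0 set to its bound (camera adjusted p = 8.0e-11). Of 15 tested members, 12 were higher, 1 was lower and 2 did not pass, and 13 were higher and 1 lower adjusted over the list alone. Cd79a, a component of the B cell receptor, was at 98.6 ± 7.71 against 2.04 ± 1.13 CPM (log2 fold change 5.58, SE 0.376). The B lineage transcription factor gene Ebf1 was at 45.3 ± 0.656 against 1.61 ± 0.570 CPM (4.80, SE 0.303). Of the immunoglobulin constant genes, Ighm was at 1123 ± 17.1 against 352 ± 47.9 CPM (1.68, SE 0.0939) and Igkc at 443 ± 1.76 against 180 ± 4.76 CPM (1.30, SE 0.0575). The T and NK lymphoid list was not called, with 1 of 13 members higher, 2 lower and 10 not passing, and 2 higher and 6 lower adjusted over the list alone. Its median was 0.02 and its mean -0.67, the sign of the test. Nkg7, a cytotoxic granule gene, rose (1.35, SE 0.0861), while the CD3 delta gene Cd3d (-1.44, SE 0.128) and the interleukin 2 receptor beta gene Il2rb (-3.12, SE 0.380) fell. Cd3d and Il2rb lost their calls with the TMRM-high libraries summed.

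Dendritic cell genes ranked lower, with 4 of 9 members lower and none higher, in both countings (camera adjusted p = 0.031, and adjusted p = 0.19 with an estimated correlation, median -0.87). The 4 that fell were MHC class II genes and the invariant chain gene, which present antigen. Cd74 was at 95.7 ± 5.41 against 263 ± 18.9 CPM (log2 fold change -1.46, SE 0.0868). H2-Aa was at 41.4 ± 3.46 against 122 ± 10.7 CPM (-1.56, SE 0.120) and H2-Ab1 at 107 ± 9.25 against 262 ± 32.0 CPM (-1.29, SE 0.114). The list lost its call without TMRM-high replicate 1 (adjusted p = 0.062) or 3 (0.051) and without TMRM-low replicate 1 (0.13) or 3 (0.12). Of the lists for non-blood cells, the endothelial one was not called, with 1 of 7 members higher and 1 lower, or 1 and 2 adjusted over the list alone. Plvap had no count in TMRM-low and 1.66 ± 0.369 CPM in TMRM-high libraries, at least 27.7-fold higher (17.9 to 29.5 with 1 library left out), and Egfl7 fell (-0.78, SE 0.115). The bone marrow stroma list was not called either; its median was -1.09 and its mean 0.23. Its 1 called member of 7, in both countings, was Vcam1, which encodes a cell adhesion molecule, at 94.1 ± 3.47 against 0.566 ± 0.534 CPM. Plvap lost its call without any 1 TMRM-high library, and Plvap and Egfl7 did not pass with the TMRM-high libraries summed.

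Of interferon response genes, 20 of 28 were lower, none was higher and 8 did not pass, and 21 were lower adjusted over the list alone (camera adjusted p = 5.6e-14, median -1.0). Irf7, a transcription factor gene of the interferon response (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), was at 9.17 ± 0.349 against 70.4 ± 13.0 CPM (log2 fold change -2.94, SE 0.194). Iigp1, an interferon-inducible GTPase gene, was at 7.02 ± 1.45 against 61.4 ± 12.3 CPM (-3.13, SE 0.249) and Ifi27 at 90.7 ± 2.68 against 273 ± 23.8 CPM (-1.59, SE 0.0875). Immediate early and dissociation response genes rose, with 18 of 23 higher, none lower and 5 not passing, and 20 higher adjusted over the list alone (camera adjusted p = 7.5e-13, median 0.97). Nfkbia, an inhibitor of NF-kappa-B, rose from 203 ± 27.0 to 616 ± 16.7 CPM (1.60, SE 0.0996). The phosphatase gene Dusp2 rose from 234 ± 15.3 to 585 ± 9.28 CPM (1.32, SE 0.0653). Zfp36, which encodes an mRNA-destabilising protein, rose from 661 ± 33.4 to 1298 ± 24.9 CPM (0.97, SE 0.0529) and Rhob from 83.8 ± 1.47 to 189 ± 5.78 CPM (1.17, SE 0.0765). Genes of this list respond to cell handling as well as to signalling.

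G2/M and mitosis genes ranked higher, with 14 of 29 higher, none lower and 15 not passing, and 20 higher adjusted over the list alone (camera adjusted p = 3.0e-08, median 0.51). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose from 85.8 ± 4.33 to 199 ± 1.32 CPM (log2 fold change 1.21, SE 0.0782). The mitotic kinase gene Plk1 rose from 38.5 ± 6.81 to 78.5 ± 2.65 CPM (1.03, SE 0.155) and Mki67 from 207 ± 11.5 to 293 ± 3.52 CPM (0.50, SE 0.0679). The list of G1/S and DNA replication genes was not called, with 3 of 32 higher and 1 lower in both countings, including Rrm2 (0.92, SE 0.106) and Pcna (0.48, SE 0.0576). HSC quiescence genes went both ways, 5 of 17 higher and 3 lower, or 6 and 6 adjusted over the list alone, and the list was not called (median 0.11, mean -0.10). Of its members, Egr1 (875 ± 28.7 against 377 ± 26.5 CPM, log2 fold change 1.21, SE 0.0654) and Btg2 (529 ± 15.2 against 206 ± 18.6 CPM, 1.36, SE 0.0786) rose. The imprinted gene Ndn fell from 11.1 ± 3.11 to 0.944 ± 0.251 CPM (-3.54, SE 0.465). Plk1 lost its call without TMRM-high replicate 1, and Plk1, Mki67, Rrm2, Pcna and Ndn did not pass with the TMRM-high libraries summed.

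Genes of the respiratory chain differed little between cells sorted by mitochondrial dye. Of the 13 mitochondrially encoded genes, 4 were higher in TMRM-high libraries and none lower, and 8 were higher adjusted over the list alone. The list missed the threshold (camera adjusted p = 0.064, median 0.21). Their share of all counts was 6.73% ± 0.328 in TMRM-high and 5.78% ± 0.467 in TMRM-low libraries, an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. mt-Nd3 was at 454 ± 4.81 against 304 ± 27.7 CPM (log2 fold change 0.58, SE 0.0747) and mt-Nd1 at 4196 ± 177 against 3369 ± 316 CPM (0.32, SE 0.0707). Nuclear genes of complex I ranked slightly lower, with 5 of 36 lower, 1 higher and 30 not passing, in both countings (camera adjusted p = 0.027, and adjusted p = 0.37 with an estimated correlation, median -0.14). Ndufs7 fell (-0.51, SE 0.0798), while Ndufa1 rose (0.60, SE 0.102). Complex I lost its call without TMRM-high replicate 2 (adjusted p = 0.092) or 3 (0.0504), without TMRM-low replicate 1 (0.13), and with the TMRM-high libraries summed (0.089). The mitochondrially encoded list passed with a stricter low-count filter (adjusted p = 0.037) and without TMRM-low replicate 2 (0.033). mt-Nd1 and Ndufa1 lost their calls without any 1 TMRM-high library, mt-Nd1 also without TMRM-low replicate 2, and Ndufs7 without TMRM-high replicate 2 or 3. None of these 3 nor mt-Nd3 passed with the TMRM-high libraries summed.

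No other mitochondrial or energy list was called. Complexes II to V had 2 of 40 genes higher and 3 lower, or 2 and 6 adjusted over the list alone, with cytochrome c (Cycs, log2 fold change 0.46, SE 0.0774) and the ATP synthase subunit gene Atp5d (-0.40, SE 0.0690) moving apart. The TCA cycle list had 1 of 19 higher and 2 lower in both countings, among them Mdh1 (-0.48, SE 0.0712), and its median (-0.02) and mean (0.01) differed in sign. Glycolysis had 2 of 21 higher and 2 lower, or 2 and 3 adjusted over the list alone, with Gpi1 higher (0.40, SE 0.0565). Fatty acid oxidation had 2 of 18 lower and none higher, or 3 adjusted over the list alone, with Eci1 lower (-0.67, SE 0.151). Mitochondrial biogenesis and dynamics had no called member among 20 in both countings. Ssbp1 had the smallest p (-0.22, SE 0.0779, edgeR adjusted p = 0.12), and the list had a median of -0.07 against a mean of 0.11. The mitochondrial ribosome had 2 of 40 lower, including Mrpl2 (-0.58, SE 0.102), and mitochondrial chaperones and proteases 1 of 16 lower, prohibitin (Phb, -0.53, SE 0.103), both unchanged when adjusted over the list alone. Without any 1 TMRM-high library Cycs, Atp5d, Eci1, Mrpl2 and Phb lost their calls. Mdh1 did so without TMRM-high replicate 3, and all 6 as well as Gpi1 did so with the TMRM-high libraries summed.

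Cytosolic ribosomal protein genes were slightly but widely lower, 38 of 56 lower and none higher, or 42 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.7e-09, and adjusted p = 0.37 with an estimated correlation, median -0.26). Their share of counts was 5.41% ± 0.148 in TMRM-high and 6.72% ± 0.220 in TMRM-low libraries (exact two-sided permutation p = 0.1, the smallest possible). Rpl3 (ENSMUSG00000060036, chromosome 15, 80077791 to 80091868) stood apart, at 573 ± 12.4 against 2767 ± 138 CPM (log2 fold change -2.27, SE 0.0520). Its processed pseudogene Rpl3-ps1 (chromosome X, 13202571 to 13203780), 94.7% of whose 31-base words also occur in Rpl3, rose from 3.62 ± 3.56 to 1747 ± 27.6 CPM. Summed with its matched pseudogenes, Rpl3 changed by -0.26 (SE 0.0468, edgeR adjusted p = 0.013), so the separate values of Rpl3 and Rpl3-ps1 are uncertain. Rplp0 (-0.61, SE 0.0489) and Rpl14 (-0.49, SE 0.0570) fell as well. Rplp0 summed with its matched pseudogenes changed by -0.50 (edgeR adjusted p = 0.00073). Ribosome biogenesis and MYC target genes were not called as a list, with 1 of 26 higher and 3 lower, or 1 and 4 adjusted over the list alone. Myc itself was at 239 ± 4.43 against 354 ± 24.7 CPM (-0.57, SE 0.0697). Rpl14 and Myc lost their calls with the TMRM-high libraries summed.

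The remaining lists were not called. The lysosome and V-ATPase list had 8 of 38 genes higher and 2 lower, or 10 and 3 adjusted over the list alone. The tetraspanin gene Cd63 was at 437 ± 5.36 against 201 ± 14.4 CPM (log2 fold change 1.12, SE 0.0699). Atp6ap2, which encodes an accessory subunit of the proton pump, was at 220 ± 12.7 against 84.3 ± 14.2 CPM (1.38, SE 0.132). Autophagy and mitophagy had 1 of 29 higher, the autophagy receptor gene Sqstm1 (1.04, SE 0.0733), and 1 lower, in both countings. The antioxidant response list had 2 of 24 higher and 4 lower in both countings, with glutathione reductase (Gsr, 1.28, SE 0.118) rising and Prdx2 falling (-0.42, SE 0.0659). Of p53 targets and apoptosis genes 2 of 21 were higher and 1 lower in both countings. Mcl1 (0.66, SE 0.0671) and Bcl2 (-0.56, SE 0.0854), both inhibitors of cell death, moved in opposite directions. Of 10 dye efflux transporters 1 passed in both countings. It was Abcb1a, a pump that exports cationic dyes, at 0.200 ± 0.129 against 5.59 ± 4.14 CPM (-4.77, SE 1.03). The list's median was 0.06 and its mean -0.51. Hypoxia response had 3 of 16 higher and 1 lower in both countings, with Vegfa at 39.6 ± 0.951 against 9.45 ± 2.62 CPM (2.07, SE 0.243). Cholesterol synthesis had 1 of 20 lower, the regulator gene Srebf2 (-0.35, SE 0.0838), and 1 higher and 2 lower adjusted over the list alone. Abcb1a and Srebf2 lost their calls without any 1 TMRM-high library, and Srebf2 also without a low-count filter and with limma voom. Prdx2 lost its call without TMRM-high replicate 2 or 3 and Bcl2 without TMRM-high replicate 1 or 3. With the TMRM-high libraries summed these 4, Mcl1 and Vegfa did not pass.

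Within groups, Spearman correlations of log2 CPM across genes, which are not independent replicates, were 0.993 to 0.994 for TMRM-high pairs and 0.938 to 0.943 for TMRM-low pairs. They were 0.933 to 0.936 for pairs between the groups. The first principal component held 47.4% of the variance and parted the groups. The second parted the TMRM-low libraries from each other, at -61.9, -20.0 and 81.7, while the TMRM-high libraries lay between -0.710 and 0.611. Levels of 90 variable segments of antigen receptors with at least 20 counts over all 6 libraries were compared. They correlated at 0.953 to 0.956 between TMRM-high libraries and at 0.490 to 0.649 between TMRM-low libraries. Segments could pass this cut through TMRM-high counts alone, and some, such as Igkv3-10 and Ighv5-9, had none in TMRM-low libraries. The cut can therefore add to this contrast. The groups did not overlap for 4842 genes (35.4%). Chance gives 10% only if all 6 libraries are independent and vary alike. The TMRM-high libraries agree far more closely and may share material, so this share does not test a group difference. Genes with at least 1 count numbered 18170 ± 458 in TMRM-high and 16728 ± 120 in TMRM-low libraries. Pseudogenes held 1.94% ± 0.102 and 3.15% ± 0.249 of the counts, and the genes AA474408 and Gm12895, chosen after their values were seen, 1.05% ± 0.133 against 2.37% ± 0.213 and 0.446% ± 0.0859 against 1.5% ± 0.237. Each of these 4 measures had an exact two-sided permutation p of 0.1, the smallest possible.

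**Figure D3:**
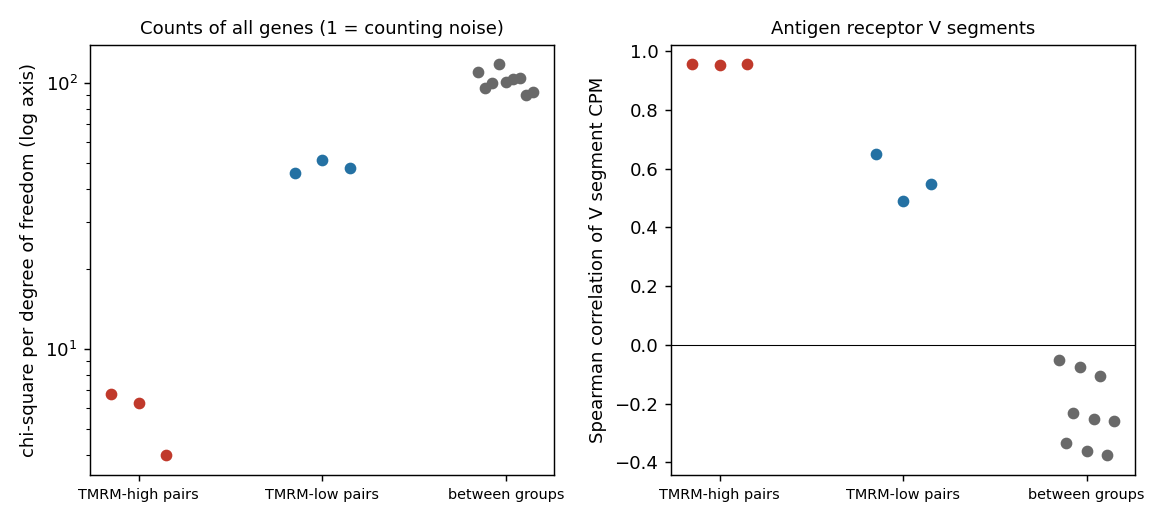
Agreement of each pair of libraries, with 1 point per pair: chi-square per degree of freedom of the counts on a log axis (left) and the Spearman correlation of V segment CPM (right). V segments were chosen by their counts over all 6 libraries. The 3 TMRM-high pairs lie at 3.98 to 6.74 on the left and at 0.953 to 0.956 on the right, apart from the TMRM-low pairs at 46.0 to 51.4 and 0.490 to 0.649.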

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

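Summing the TMRM-high libraries and summing ribosomal protein genes with their pseudogenes were chosen after the data were seen; the other alternatives were planned. Counts of higher and lower genes stayed within 1.5 times of 798 and 700 under the other scalings, filters, limma voom, composition removal and pseudogene sums. DESeq2 called 1324 and 1337, a minimum of 2-fold left 434 and 300, an adjusted p of 0.10 gave 1138 lower, and the TMRM-high libraries summed into 1 gave 86 and 42, all of them among the 1498 main calls. Leaving out 1 library gave 250 to 1398 higher and 181 to 1174 lower genes, fewer without a TMRM-high library and more without a TMRM-low one. The model uses 1 estimate of spread for both groups, whose biological coefficients of variation were 7.24% in TMRM-high and 41.5% in TMRM-low libraries. The counts therefore depend on taking the TMRM-high libraries as 3 replicates. Passing members of the lists came to 114 to 288 over left-out libraries and 57 with the TMRM-high libraries summed. The cause was not tested.

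With the replicate block 582 genes were higher and 449 lower, and complex I (adjusted p = 0.0561) and dendritic cell (0.0866) lists and the named genes Eci1, Abcb1a and Srebf2 lost their calls. Deviations of same-numbered libraries from their group means correlated at -0.0139, 0.0165 and 0.0210, and libraries did not all correlate best with their own number. This gives no sign that the numbers pair the libraries. It cannot exclude pairing, because the TMRM-high libraries differ little (biological coefficient of variation 7.24%) and leave little to correlate.

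Lists called higher stayed at 7 or 8 and lower at 4 to 6 except with an estimated correlation (6 and 3) and fry (12 and 13). With an estimated correlation adjusted p was 0.367 for complex I, 0.367 for ribosomal proteins, 0.0821 for megakaryocyte and 0.187 for dendritic cell genes. With the TMRM-high libraries summed, complex I had 0.0893, and no list passed once the correlation was also estimated. The mitochondrially encoded list passed with the stricter filter (0.0373). Over left-out libraries adjusted p ran from 0.0328 to 0.235 for mitochondrially encoded, 0.0152 to 0.126 for complex I and 0.0408 to 0.126 for dendritic cell genes. Fry added complexes II to V (0.0250), fatty acid oxidation (0.0274), mitochondrial ribosome (0.0121), ribosome biogenesis (0.030), cholesterol synthesis (0.0442), sort markers (0.00046) and T and NK (0.0121) as lower, and HSC quiescence (0.0078), G1/S (0.030), lysosome (0.0031), p53 (0.010) and endothelial (0.0078) as higher.

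The lowest Spearman correlation of TMRM-low pairs (0.938) was 0.923 without a low-count filter and 0.921 with the stricter one; the cause was not tested. No named gene called in the main test changed sign under any alternative. Some lost their calls with the TMRM-high libraries summed, where the lone library is assumed to vary like the TMRM-low ones. Their log2 fold changes moved by a median of 0.01, since summing leaves the TMRM-high level nearly unchanged by construction. At 14270069 to 22070594 counts per library, genes with few counts are the least precise.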

Other observations

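The tests of explanations in this part were chosen after the results were seen, and the genes of the first 2 paragraphs were chosen after their values were seen. Some genes outside the fixed lists were higher in TMRM-high libraries: Cxcl10 at 40.0 ± 1.56 against 3.72 ± 0.855 CPM, Cxcl2 at 66.7 ± 1.75 against 9.45 ± 4.10 CPM, Ccl4 at 400 ± 10.3 against 174 ± 12.1 CPM, Tnfaip3, an inhibitor of NF-kappa-B signalling, at 170 ± 8.67 against 30.8 ± 6.20 CPM, and the early activation marker Cd69 at 313 ± 16.1 against 74.0 ± 16.9 CPM. Cxcl10 is inducible by interferon, and it rose (log2 fold change 3.42, SE 0.250) where other interferon-inducible genes fell, among them Ifitm3 (-1.86, SE 0.0699), Tgtp1 (-2.35, SE 0.114) and Rtp4 (-2.58, SE 0.164). Tgtp1 has a close copy, Tgtp2, so its counts are uncertain. Ccl5, like Cxcl10, Cxcl2 and Ccl4 a chemokine gene (5.41 ± 1.61 against 59.1 ± 2.24 CPM), and Ltb (19.0 ± 3.33 against 90.6 ± 6.72 CPM) were lower in TMRM-high libraries.

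Immunoglobulin constant genes moved apart: Ighg2c was at 62.9 ± 2.03 against 4.80 ± 2.18 CPM, while Igha was at 41.4 ± 2.60 against 118 ± 13.9 CPM. Mzb1, a gene of antibody-secreting cells, was at 38.9 ± 2.91 against 3.19 ± 0.929 CPM. Fcnb, a ficolin gene of the granulocyte and monocyte lineage, rose by a log2 of 7.51 (SE 0.280). The 90 V segments summed to 582 ± 14.4 CPM in TMRM-high and 103 ± 18.0 CPM in TMRM-low libraries. A large part was the segment Iglv1, at 250, 267 and 264 CPM in TMRM-high and 12.3, 9.48 and 11.6 CPM in TMRM-low libraries. Some segments, such as Igkv4-72, went the other way, so the sum does not describe each segment. Apart from the V segments, all 14 genes of these paragraphs passed edgeR's test (adjusted p at most 0.0015). Cxcl10, Cxcl2, Igha and Mzb1 did not pass with the TMRM-high libraries summed.

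The first pattern weighed is the close agreement of the TMRM-high libraries. A difference in depth is argued against, because with all libraries thinned to 1 total the lowest chi-square per degree of freedom of TMRM-low pairs was still 7.27 times the highest of TMRM-high pairs. Libraries made from shared cells or RNA remain a candidate explanation: V segments, which differ between single lymphocytes, correlated at 0.953 or more between TMRM-high libraries, although their higher level there also raises such a correlation. A more uniform stem cell population as the whole cause would leave V segments, which differ between single lymphocytes, as variable in TMRM-high as in TMRM-low libraries. At matched levels of 1 to 20 CPM their median coefficient of variation was 2.03 times higher in TMRM-low libraries, which runs against it. The quartiles overlapped (21.6% to 58.0% over 14 segments against 8.41% to 25.3% over 48), and the segments compared were not the same. These values therefore do not exclude it as the whole cause. The groups also differ in genes detected (18170 against 16728) and in the share of pseudogenes (1.94% against 3.15%); the labels give no preparation batch, and a difference in library quality between the groups was not tested and stays open. If the TMRM-high libraries share material, the comparison rests on fewer independent samples than 3 against 3.

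The second pattern is the rise of lineage genes with the fall of HSC identity genes and Ly6a. Interferon response genes fell in the same libraries (20 of 28 lower). The falls of Ly6a and of Ifitm1, an HSC identity gene, were not tested apart from that change. A lower share of stem cells that raises every other cell type alike is argued against only weakly. The dendritic cell list had a median of -0.87 where the B lymphoid list had 4.80, with quartiles apart. The 4 called dendritic cell genes of 9 were MHC class II genes and the invariant chain gene, so the list may follow these genes rather than dendritic cells. It lost its call with an estimated correlation (camera adjusted p = 0.19) and with some single libraries left out. T and NK genes did not rise alike either, with 1 of 13 higher and 2 lower, or 2 and 6 adjusted over the list alone. That list was not called. The NK receptor genes Klra8, Klra4, Klra7 and Ncr1 were lower too, but they were named for the size of their decrease. Committed granulocytic, erythroid, basophil and B lineage cells in the TMRM-high gate stay open as an explanation. Of the 62 tested members of these 4 lists 64.5% were higher and 8.06% lower, but the lists were picked because they rose, so this share does not test it. Of megakaryocyte genes 3 of 16 were higher and 1 lower. Abundant transcripts of such cells were present in TMRM-high libraries, with Mpo at 5534 CPM, Elane at 3036 CPM and Ighm at 1123 CPM. TMRM-low libraries held them too, at 1844, 232 and 352 CPM. These genes are part of the pattern and do not test it. The sort for cells without lineage markers would remove mature cells, none of the 62 genes is in another list, and 37 had at least 5 CPM in TMRM-low libraries. A difference between HSCs of high and low membrane potential was not tested apart from this and stays open.

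The third pattern is the lower level of ribosomal protein genes, whose list was not called with an estimated correlation (camera adjusted p = 0.37). For Rpl3, reads placed on its pseudogene are a candidate explanation, since Rpl3 summed with its pseudogenes changed by only -0.26 against -2.27 alone. For the other 56 genes this is argued against, because their median was -0.28 after summing (quartiles -0.39 to -0.22) and -0.25 before. No biological explanation was tested for this pattern.

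The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1498 genes with edgeR and the highest of the other splits 0, and it was the only 1 of the 10 with as many; at an unadjusted p under 0.05 the other splits gave up to 250 genes against 3495, and DESeq2 called up to 2 against 2661. For gene lists the real split called 13 and the highest other split 7, and again 1 of the 10 gave as many. Every other split puts TMRM-high and TMRM-low libraries into the same group, which widens the spread within groups. Few gene calls there follow from the parting of the TMRM-high from the TMRM-low libraries, whatever its source.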
